A study of Mus musculus with 12 samples.

How the data were processed

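Erythroblasts were sorted from the spleens of male mice on day 3 after phenylhydrazine, a drug that destroys red cells and sets off stress erythropoiesis in the spleen. The mice had been fed a selenium-adequate or a selenium-deficient diet for 3 months. Total RNA (5 ng per sample) of proerythroblasts, the earlier stage, and of basophilic erythroblasts, the next stage, was labelled with biotin and hybridised to Affymetrix whole-transcript arrays. There were 12 arrays in 4 groups, 3 arrays per group. The number of arrays limits the precision of every value.

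The authors deposited log2 expression values made with Affymetrix Expression Console. The labels give no version, background correction, summarisation or normalization method for these values. The medians and quartiles of the 12 arrays differed, so the deposited log2 values had not been brought to the same distribution. No further transformation was applied for the comparisons reported.

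Samples were grouped by their titles. The description of deficient basophilic replicate 3 names proerythroblasts, in conflict with its title and its cell type label. It was kept as basophilic, and across all features it correlated with deficient basophilic replicate 1 at r = 0.986. Its r was 0.910 with deficient basophilic replicate 2, an array that stood apart. With deficient proerythroblast replicates 1, 2 and 3 it was 0.969, 0.962 and 0.969.

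The table held 72688 features, of which 186 were controls. Exactly 1 gene was named for 31238 features, several genes for 1512 and no gene for 39752. The symbols of 1761 features were updated to the present symbol. This gave 30686 genes, and for the 437 genes with more than 1 feature the feature with the highest mean over the 12 arrays was used. A gene was tested when its value exceeded 5.30, the median of all values, in at least 3 arrays, which left 20120 genes. The major adult globin features name several genes and were therefore outside the gene comparisons.

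Each gene was fitted with limma 3.58.1 in R 4.3.3, with a mean per group and eBayes defaults, and python 3.11.15 prepared the tables. There were 6 comparisons: the diet effect in proerythroblasts, in basophilic erythroblasts and averaged over both stages, the stage effect on each diet, and the diet by stage interaction, which is the diet effect in basophilic erythroblasts minus that in proerythroblasts. All p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Words such as rose and fell are used of genes past that threshold.

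For each comparison the text names the 10 highest and the 10 lowest log2 fold changes among genes past the threshold whose 3 arrays in 1 group did not overlap the 3 in the other. For the diet effect over both stages this was required within each stage. The interaction had no overlap condition, and symbols of predicted or unnamed genes were left out. Where fewer than 5 genes passed, the 10 genes with the smallest p are given as values that did not pass. Every measured selenoprotein gene is covered in the diet comparisons, and up to 4 members with the smallest adjusted p of each list described.

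There were 33 gene lists. They cover selenoproteins, selenocysteine synthesis, NRF2 and antioxidant genes, heme synthesis, globins, red cell membrane proteins, erythroid regulators, progenitor genes, BMP and hedgehog signalling, erythropoietin and STAT5 signalling, iron, S phase, G2 and mitosis, ribosomal proteins, ribosome biogenesis, the interferon response, oxidative phosphorylation, the integrated stress and unfolded protein responses, p53 targets, autophagy and enucleation, eicosanoids and lipid peroxidation, glycolysis and hypoxia, cholesterol synthesis, replication-dependent histones, MHC antigen presentation, and markers of macrophages, neutrophils, megakaryocytes, B cells, T and NK cells, stroma, and mast cells and basophilic granulocytes. Genes encoded by the mitochondrial genome had only 2 tested members, fewer than the minimum of 5, and were not tested as a list. Lists were tested with camera of limma at a preset correlation of 0.01, again with an estimated correlation, and with fry. Benjamini-Hochberg adjustment was over the lists within a comparison. Fry values are printed only for some lists of the diet effect in proerythroblasts. The groups, comparisons, tests, lists and rule for named genes were fixed before the data were examined.

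Alternatives were no filter and a stricter filter on dim features (a value above 6.62), quantile normalization, median centring, trended and robust variance, array weights, the replicate number as a fixed or a random block, the mean of a gene's features, every feature by itself, a 1.5-fold threshold, an adjusted p of 0.1, a fit of the arrays of the contrast only, and leaving out each array in turn. Chosen after seeing the data were a fit without replicate 2 of both basophilic groups, whose arrays stood apart, and a block of the replicate number within each stage.

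The labels do not say that a replicate number marks an animal or a sort shared between groups. After removing each group's mean, arrays of the same number in the 2 diets correlated across genes at 0.72, 0.78 and 0.54 in basophilic erythroblasts and at 0.46, 0.18 and 0.52 in proerythroblasts. Differing numbers gave values from -0.40 to 0.08 in proerythroblasts. In basophilic erythroblasts replicate 2 stood apart from the others, while adequate 1 with deficient 3 gave 0.60 and adequate 3 with deficient 1 gave 0.51, so a pairing of replicates 1 and 3 is not shown there. Blocked values stand beside only some of the results they change. Between stages the same correlations were 0.21, -0.07 and -0.17 on the adequate diet and 0.25, 0.20 and 0.10 on the deficient diet.

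The fits were tested on simulated data with changes added to random genes among the 20120. These data held normal noise independent between genes and arrays, 200 changed genes per comparison and no outlying array. The shares found are therefore not the power of the real comparisons. At a true change of 2-fold, 58.2% of the changed genes were found for the diet effect in proerythroblasts, 65.7% for that in basophilic erythroblasts, 82.1% for that over both stages, 62.7% for the stage effect on the adequate diet, 65.7% for that on the deficient diet and 22.4% for the interaction. At 4-fold these shares were 89.4%, 92.4%, 97.0%, 98.5%, 95.5% and 75.8% in the same order.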

Results

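Expression was measured in 12 arrays of splenic erythroblasts from mice recovering from phenylhydrazine-induced anaemia, 3 each of proerythroblasts and basophilic erythroblasts on a selenium-adequate and on a selenium-deficient diet. The basophilic arrays had a higher background and a narrower range of values than the proerythroblast arrays. The median of the GC background features averaged 3.43 in adequate and 3.41 in deficient proerythroblasts, and 3.87 and 4.06 in adequate and deficient basophilic erythroblasts. Within the basophilic groups, replicate 2 stood apart on both diets, with a background of 4.19 (adequate) and 4.70 (deficient) and an interquartile range of 2.25 and 2.17.

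**Figure D1:**
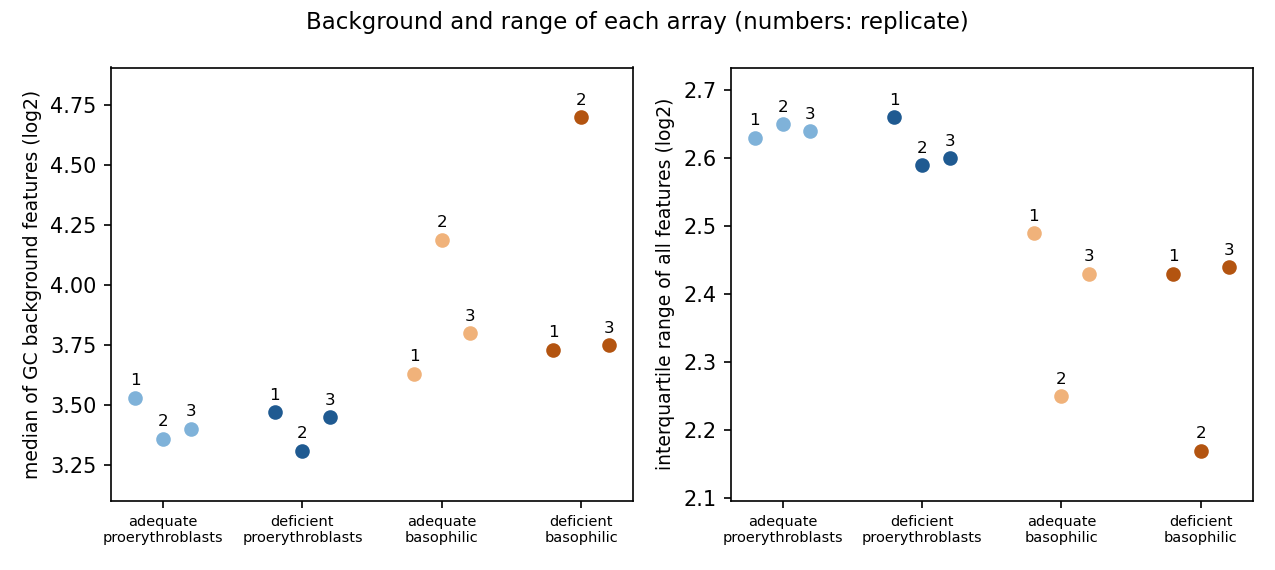
Median of the GC background features (left, log2) and interquartile range of all features (right, log2) of each of the 12 arrays, by group, with the replicate number above each point. Replicate 2 of both basophilic groups has the highest background, 4.19 and 4.70, and the narrowest range, 2.25 and 2.17.

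The first comparison asked what the deficient diet changed in proerythroblasts. Kit, the receptor for stem cell factor, fell by 2.18 on the log2 scale (SE 0.16, adjusted p = 4.67e-05), and Myb, a transcription factor of progenitors, fell by 2.06 (SE 0.19, adjusted p = 2.55e-04). Alas2, the erythroid enzyme of the first step of heme synthesis, rose by 1.67 (SE 0.19, adjusted p = 8.89e-04). Tmod1, a capping protein of the red cell skeleton, rose by 1.79 (SE 0.12, adjusted p = 3.47e-05), and Slc4a1, the band 3 anion exchanger, by 1.39 (SE 0.13, adjusted p = 2.55e-04). In all, 810 of 20120 genes passed, 255 higher and 555 lower on the deficient diet (limma, n = 3 per group), and 2811 had an unadjusted p under 0.05.

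The largest increases in proerythroblasts were of Ttc39aos1, an antisense transcript, by 3.65 (SE 0.59), the adhesion receptor gene Adgrg2 by 2.79 (SE 0.24), and Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, by 2.76 (SE 0.57, adjusted p = 0.0177). Ankrd36, the theta globin genes Hbq1b and Hbq1a, whose near-identical copies share sequence, Rragd, Cish, H1f2 and the phosphatase gene Cdc25b rose by between 2.12 and 2.43. The largest decreases were of Sh2d4a, by -2.94 (SE 0.20), and of Gatm, an enzyme of creatine synthesis, by -2.83 (SE 0.32). Mettl8, the chaperone gene Hsph1, Gpc4, Sfrp4, Adgrg7 and Gdpd1 fell, with log2 changes from -2.42 to -1.87. The rule for naming required the 3 deficient arrays of each of these genes to lie all above or all below the 3 adequate arrays. Of the 21 genes named by this rule or as selenoproteins that passed, 19 kept their call whichever array was left out, and 18 of these in every alternative. Gdpd1 lost its call with the mean of a gene's features (-0.73, adjusted p = 0.0558), which also ended it over both stages (-0.56, adjusted p = 0.0546). Cdkn1a lost it without any proerythroblast array other than deficient replicate 2, with adjusted p-values up to 0.087 (without deficient replicate 3), and H1f2 without adequate replicate 2 (0.0637) or deficient replicate 3 (0.0522).

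By list, 4 of 18 progenitor genes fell in proerythroblasts and 14 did not pass. Besides Kit and Myb, those that fell were the cell cycle kinase gene Cdk6 (-1.36) and Sox4 (-0.88). In all, 5 fell when adjusted over the list alone. The progenitor list was lower than other genes by camera (adjusted p = 1.58e-04) and had an adjusted p of 0.0418 with an estimated correlation. Of 26 autophagy and enucleation genes, 3 rose (7 adjusted over the list alone), Ube2o (1.39), Diaph3 (0.66) and Xpo7 (1.02), and the list was higher by camera (adjusted p = 3.80e-05, and 0.0418 with an estimated correlation). The medians were -0.20 for the progenitor and 0.30 for the autophagy and enucleation genes. They use the proerythroblast arrays alone, so leaving out replicate 2 of both basophilic groups could not move them and changed only the error. In that fit 6 progenitor genes fell and 11 autophagy and enucleation genes rose (2 fell). Camera then gave an adjusted p of 8.01e-04 and 6.49e-04, but 0.454 for both with an estimated correlation. Of 17 heme synthesis genes, 6 rose (8 adjusted over the list alone), among them the mitochondrial iron importer gene Slc25a37 (1.29) and Fech (1.26), the enzyme that inserts iron into heme. Of 23 red cell membrane genes, 6 rose (10 adjusted over the list alone), with the spectrin gene Sptb (1.03) and Epb42 (1.05) besides Tmod1 and Slc4a1. Of the 5 measured globin genes, Hbq1a and Hbq1b rose. These 3 lists were higher by camera (adjusted p = 5.44e-08, 1.01e-12 and 2.85e-05 for heme synthesis, membrane and globins), but not with an estimated correlation (adjusted p = 0.126, 0.231 and 0.126). Fry gave them an adjusted p of 0.00517, 0.0132 and 6.51e-04. For the progenitor and the autophagy and enucleation lists fry gave 6.51e-04 and 0.00178.

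Among regulators in proerythroblasts, E2f2, a cell cycle transcription factor of erythroblasts, rose by 1.90, and Sox6 by 1.07. Of 20 erythroid regulators, 3 rose and 2 fell (camera adjusted p = 0.106). Of 21 genes of erythropoietin and STAT5 signalling, 5 rose and 1 fell (5 and 2 adjusted over the list alone). The survival gene Bcl2l1 (1.32), the kinase gene Pim1 (1.69) and the feedback inhibitor gene Cish (2.18) rose, and the phosphatase gene Ptpn6 (-1.22) fell. The list as a whole had a camera adjusted p of 0.082 and a fry adjusted p of 0.0152. Of 21 p53 targets, 3 rose, namely Eda2r (1.11), Fas (0.75) and Cdkn1a (camera adjusted p = 2.73e-04, but 0.126 with an estimated correlation). Of 22 iron genes, 5 rose, with Slc25a37 and Ncoa4 (1.24), which carries ferritin to autophagy, and 2 fell (camera adjusted p = 0.157). Of 32 NRF2 and antioxidant genes, 5 rose and 2 fell (6 and 4 adjusted over the list alone), with Me1 (0.66), Prdx2 (0.56) and Nqo1 (1.13) up and Pgd (-0.51) down (camera adjusted p = 0.0365, but 0.251 with an estimated correlation). Of 33 ribosome biogenesis genes, 3 fell (10 adjusted over the list alone), Utp20 (-0.58), Polr1b (-0.75) and Nop2 (-0.81). The list was lower by camera (adjusted p = 3.17e-09, but 0.302 with an estimated correlation). Of 10 replication-dependent histone genes, H1f2 and H2ac18 (1.43) rose (camera adjusted p = 1.55e-06, but 0.306 with an estimated correlation). Without replicate 2 of both basophilic groups, 16 ribosome biogenesis genes fell (0 rose) and 9 histone genes rose (0 fell). Camera with an estimated correlation then gave an adjusted p of 0.454 and 0.0562. With all arrays, fry gave an adjusted p of 0.0175 for p53 targets and 0.086 for NRF2 and antioxidant genes. For ribosome biogenesis and histone genes fry gave 0.0808 and 0.0987.

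Markers of neutrophils had a median 0.44 higher in deficient proerythroblasts, and 1 of 18, Mmp9 (0.57, adjusted p = 0.0373), passed. The list was higher by camera (adjusted p = 0.0103, but 0.658 with an estimated correlation and 0.387 with fry). Camera placed this list lower in basophilic erythroblasts on both diets, so its higher median here runs against the stage effect. The proerythroblast count rose to 3285 (1400 higher, 1885 lower) without replicate 2 of both basophilic groups and to 2233 with a replicate block within each stage, both chosen after seeing the data. Array weights gave 8008, the proerythroblast arrays alone 2417 and an adjusted p of 0.1 gave 1286. It was 314 without adequate proerythroblast replicate 1, 341 without adequate replicate 2, 454 without deficient replicate 2, 323 without deficient replicate 3, and 1808 without deficient basophilic replicate 2. Basophilic arrays do not enter these estimates, so leaving them out changes calls only through the error estimate, which all groups share. Of the 49 list members named and called in this comparison, 20 kept their call whichever array was left out, among them Alas2, Slc25a37, Fech, Tmod1, Slc4a1, Sptb, Epb42, Cdk6, Sox4, E2f2, Bcl2l1, Pim1, Ptpn6, Eda2r and Ncoa4. The other 29 included Ube2o, Diaph3, Xpo7, Fas, Me1, Prdx2, Nqo1, Pgd, Utp20, Polr1b, Nop2, H2ac18 and Mmp9, whose highest adjusted p-values on leaving out an array were 0.0748, 0.0807, 0.142, 0.0568, 0.099, 0.0979, 0.147, 0.142, 0.0894, 0.134, 0.184, 0.123 and 0.184. Fas had an adjusted p of 0.418 with the mean of a gene's features.

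The diet is known to act on selenoproteins, which carry selenium as selenocysteine. Selenow was the only 1 of the 21 tested selenoprotein genes past the threshold in proerythroblasts: it fell by 1.29 on the log2 scale (SE 0.16, adjusted p = 0.00129), from a mean of 9.58 (SD 0.09, n = 3) to 8.30 (SD 0.28, n = 3), with all 3 deficient arrays below all 3 adequate ones. Adjusted over the list alone, 3 fell. Selenoh had -0.56 (adjusted p = 0.0704), Selenoo -0.47 (adjusted p = 0.0675), Selenoi -0.47 (adjusted p = 0.232) and Gpx1, glutathione peroxidase 1, -0.39 (adjusted p = 0.287). Txnrd1, a thioredoxin reductase, had 0.80 (SE 0.38, adjusted p = 0.391). In basophilic erythroblasts Selenow had -0.29 (SE 0.16, adjusted p = 0.867), Gpx1 -0.39 (adjusted p = 0.711), Selenot 0.65 (adjusted p = 0.151), Selenos 0.90 (adjusted p = 0.465) and Gpx4 0.49 (adjusted p = 0.542), and no selenoprotein gene passed. The difference between the stages in the Selenow effect was 0.99 (SE 0.22, adjusted p = 0.0968).

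Averaged over both stages Selenow fell by 0.79 (SE 0.11, adjusted p = 0.00510), and Selenot rose by 0.40 (SE 0.09, adjusted p = 0.0474). The call of Selenot ended without any single array other than adequate or deficient basophilic replicate 2 (adjusted p up to 0.14), and under quantile normalization, median centring, no filter, a 1.5-fold threshold, trended variance and a random block. The remaining 19 genes did not pass over both stages; Dio2, Gpx2, Gpx3, Msrb1, Selenof, Selenok, Selenom, Selenon, Selenop, Sephs2, Txnrd2 and Txnrd3 had estimates from -0.20 to 0.16 there. The estimates of Dio2, Gpx3, Selenop and Txnrd3 in proerythroblasts, of Selenon and Txnrd2 in basophilic erythroblasts, and of Gpx2 over both stages changed sign under quantile normalization or median centring. With a replicate block within each stage, chosen after seeing the data, Selenoh (-0.56, adjusted p = 0.0134), Selenoo (-0.47, adjusted p = 0.0282) and Txnrd1 (0.80, adjusted p = 0.019) also passed in proerythroblasts, and Selenot (0.65, adjusted p = 0.0347) and Selenos (0.90, adjusted p = 0.0398) in basophilic erythroblasts. Over both stages Selenoh (-0.42), Selenoo (-0.31), Gpx1 (-0.39), Gpx4 (0.32) and Txnrd1 (0.63) then passed, and the interactions of Selenow (0.99, adjusted p = 0.0413) and Selenoi (0.90, adjusted p = 0.0493). The list of selenoproteins had a camera adjusted p of 0.155 in proerythroblasts and 0.328 in basophilic erythroblasts. Without replicate 2 of both basophilic groups, also chosen after seeing the data, 2 selenoprotein genes rose and 4 fell in proerythroblasts. In basophilic erythroblasts 3 rose and 0 fell in that fit. Camera then gave the list an adjusted p of 0.302 and 0.31. Of 9 genes of selenocysteine synthesis, Pstk, the kinase that acts before selenium is added, was the only 1 to fall in proerythroblasts (-0.66, adjusted p = 0.0283), a call that ended under quantile normalization and on leaving out single arrays (adjusted p up to 0.147). With the block within each stage Eefsec, the elongation factor for selenocysteine, also passed there (-0.46, adjusted p = 0.0455, against 0.202 without a block).

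**Figure D2:**
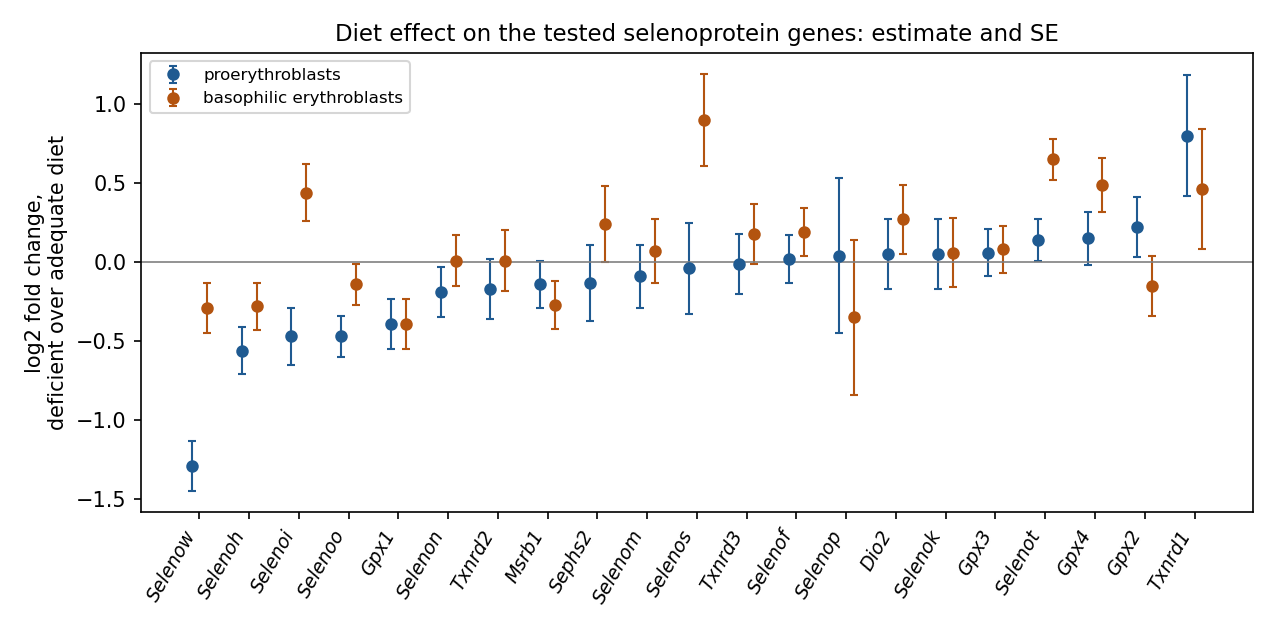
Log2 fold change of the deficient over the adequate diet, with its SE, for the 21 tested selenoprotein genes in proerythroblasts and in basophilic erythroblasts (n = 3 arrays per group). Selenow has the lowest value in proerythroblasts, -1.29, and Gpx1 has -0.39 in basophilic erythroblasts.

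In basophilic erythroblasts 4 genes passed for the diet, 2 higher and 2 lower, with 1304 at an unadjusted p under 0.05. The arrays of the diets did not overlap in 8.0% of the genes, against 10% by chance and 31.1% in proerythroblasts. Dstn, which encodes the actin-severing protein destrin, rose by 1.98 (SE 0.25, adjusted p = 0.0383), and Tac2, a tachykinin gene, fell by 1.26 (SE 0.17, adjusted p = 0.0495). The other two are unnamed transcripts, given after their values were seen: 4930542N06Rik rose by 1.61 (SE 0.17, adjusted p = 0.0167) and 4930430F08Rik fell by 1.41 (SE 0.18, adjusted p = 0.0383). Among genes that did not pass, the smallest p-values were those of Ralgapa2 (-1.02, adjusted p = 0.0613), Rdm1 (-1.12, adjusted p = 0.0684) and the glutathione synthetase gene Gss (1.17, adjusted p = 0.0889), then Afmid (-0.98), Asb3 (-0.90), Sri (-1.11), Cep128 (-0.76), Ints13 (0.65), Hadh (1.82) and Erlec1 (-0.80), with adjusted p from 0.125 to 0.134. With the replicate number as a block, Ralgapa2 (0.0291), Rdm1 (0.0386), Gss (0.0291), Asb3 (0.0357), Sri (0.0256) and Hadh (0.0142) had adjusted p-values under the threshold.

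Genes of S phase had a median change of -0.56 and genes of G2 and mitosis of -0.47 in deficient basophilic erythroblasts, with none of 42 and of 51 members past the threshold. Camera placed both lower than other genes (adjusted p = 7.72e-14 and 4.34e-09), but not with an estimated correlation (adjusted p = 0.694 for both). The medians were -0.32 for S phase and -0.17 for G2 and mitosis without replicate 2 of both basophilic groups. Of 32 NRF2 and antioxidant genes, none passed over all genes and 7 were higher when adjusted over the list alone, with Gss, Pgd (0.60) and Nqo1 (0.98) first (camera adjusted p = 4.20e-04, but 0.233 with an estimated correlation). Interferon response genes had a median of -0.25 with none of 28 past the threshold (camera adjusted p = 2.49e-04, but 0.389 with an estimated correlation). Neutrophil markers had a median of 0.22 here, with none of 18 past the threshold (camera adjusted p = 0.0109, but 0.730 with an estimated correlation), and megakaryocyte markers a median of 0.21, with none of 11 (camera adjusted p = 0.00712, but 0.320 with an estimated correlation). The calls of Dstn and Tac2 ended on leaving out any single array other than basophilic replicate 2 of either diet, with adjusted p up to 0.223 and 0.277 (both without adequate basophilic replicate 1), and at 0.906 with the basophilic arrays alone. The call of Dstn also ended under median centring (0.0507), and that of Tac2 without the filter (0.053), with a random block (0.0533) and with every feature by itself (0.0507). The basophilic count was 19 with the replicate block, 50 under quantile normalization, 155 with array weights, 7 at an adjusted p of 0.1, and 0 with the basophilic arrays alone. Leaving out an array moved it between 0 and 289, the highest without deficient basophilic replicate 2.

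Without replicate 2 of both basophilic groups, a choice made after seeing the data that leaves 2 arrays per group, 420 genes passed in basophilic erythroblasts, 275 higher and 145 lower. The largest increases there were of Scai (2.70), Ankrd36 (2.47), Lrp6 (2.39), Tnfrsf13c (2.39) and Plxnc1 (2.38). The largest decreases were of the sulfite oxidase gene Suox (-1.88), the interferon-induced gene Isg15 (-1.74), the asparagine synthetase gene Asns (-1.64) and Chac1 (-1.63), which degrades glutathione. Dstn had 2.26 (adjusted p = 0.00602) and Tac2 -1.50 (adjusted p = 0.00238) in this fit. With a replicate block within each stage 295 genes passed, 102 higher and 193 lower, so the balance of directions turned between these fits.

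Averaged over both stages, 515 genes passed for the diet, 192 higher and 323 lower on the deficient diet. The largest increases and decreases named here are among genes whose arrays did not overlap between the diets within each stage. That condition by itself favours genes that differ in both stages. Cdkn1a had the largest increase, 2.27 (SE 0.40, adjusted p = 0.0117), followed by Ankrd36 (2.18), the calcium channel gene Cacna1c (1.86), Adgrg2 (1.71), Tspan14 (1.61), the interferon gamma receptor gene Ifngr2 (1.49), Dstn (1.41), Hbq1a (1.25), Hbq1b (1.23) and Acadsb (1.18). The largest decreases were of Gatm (-1.99), Sh2d4a (-1.73), Gpc4 (-1.62), C1qtnf12 (-1.56), the selenium-binding protein genes Selenbp1 (-1.50, adjusted p = 0.00761) and Selenbp2 (-1.46, adjusted p = 0.00721), which are not selenoproteins, Mettl8 (-1.48), Suox (-1.37), Gdpd1 (-1.29) and Aldh1a7 (-1.27). Of 32 NRF2 and antioxidant genes, 5 rose and none fell, with Me1 (0.56), Gss (0.72), the quinone reductase gene Nqo1 (1.06) and Srxn1 (1.09), which repairs peroxiredoxins (camera adjusted p = 4.74e-04, but 0.113 with an estimated correlation). The call of Srxn1 ended without single arrays, with adjusted p up to 0.0568. Of 17 heme synthesis genes, 4 rose, and of 18 progenitor genes, 3 fell, with Kit at -1.11 and Myb at -0.98 (camera adjusted p = 3.87e-04 and 0.00450, but 0.256 and 0.113 with an estimated correlation). Markers of other cells were higher in the same comparison: neutrophil (median 0.25, 1 of 18 past the threshold), megakaryocyte (2 of 11) and mast cell and basophilic granulocyte markers (0 of 5). Their camera adjusted p was 0.00131, 0.0251 and 0.048, but 0.61, 0.221 and 0.554 with an estimated correlation.

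The diet effects of the stages correlated across 20120 genes at Pearson r = 0.234 and Spearman 0.166, where genes are not independent replicates. The jackknife SE of r over the arrays was 0.132, and r fell to 0.113 without deficient basophilic replicate 3. Of the genes called in proerythroblasts and in basophilic erythroblasts, 1 higher and 2 lower genes were shared. Without replicate 2 of both basophilic groups the shared genes were 115 higher, against 19.1 for independent lists, and 61 lower, against 13.6, and r was 0.355. Both comparisons share each gene's error estimate, so more overlap than independent lists give does not by itself show a shared diet effect. The count over both stages was 876 with the replicate block and 2049 with the block within each stage, 2303 without replicate 2 of both basophilic groups, 2469 with array weights, 931 at an adjusted p of 0.1 and 307 at a 1.5-fold threshold. It was 259 and 266 without adequate basophilic replicates 1 and 3, 245 and 249 without adequate proerythroblast replicates 1 and 2, 335 and 248 without deficient proerythroblast replicates 2 and 3, 306 without deficient basophilic replicate 3, and 1505 without deficient basophilic replicate 2. Ifngr2 lost its call without any of 10 single arrays, with adjusted p up to 0.0949.

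Whether the diet acted differently in the stages was tested by the interaction, in which 61 genes passed, 32 with a higher and 29 with a lower diet effect in basophilic erythroblasts. Kit fell on the deficient diet in proerythroblasts from a mean of 9.10 (SD 0.21) to 6.92 (SD 0.18). It was 6.34 (SD 0.15) and 6.30 (SD 0.21) in adequate and deficient basophilic erythroblasts, which gives an interaction of 2.13 (SE 0.23, adjusted p = 0.00510, n = 3 per group). Myb (2.15, adjusted p = 0.00849), Sh2d4a (2.41, adjusted p = 0.00594) and Prelid2 (1.83) were also higher in the interaction. In the other direction, Tmod1 was 7.80 (SD 0.10) and 9.58 (SD 0.08) in adequate and deficient proerythroblasts, and 10.42 (SD 0.11) and 10.33 (SD 0.08) in basophilic erythroblasts, an interaction of -1.88 (SE 0.16, adjusted p = 0.00220). Gch1 (-2.49), Cdc25b (-2.11), Hbq1b (-2.03), Hbq1a (-1.88) and E2f2 (-1.58) were also lower in the interaction.

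Those 10 genes kept their interaction call whichever array was left out. The other 10 named genes, Itga5 (1.76), Sfrp4 (1.76), Hsph1 (1.73), the endoglin gene Eng (1.66), Cd248 (1.52), Wdsub1 (1.44), Adgrg2 (-2.16), Fhdc1 (-2.15), Alas2 (-1.67) and Slc6a9 (-1.55), lost it on leaving out at least 5 of the arrays, with adjusted p up to 0.166 (Sfrp4, without adequate proerythroblast replicate 1), and Slc6a9 had 0.335 with the mean of a gene's features. Of 18 progenitor genes, 3 were higher in the interaction (4 adjusted over the list alone), Kit, Myb and Sox4 (1.08), and the list was higher by camera (adjusted p = 6.04e-05, and 0.0330 with an estimated correlation). Of 26 autophagy and enucleation genes none passed and 4 were lower adjusted over the list alone, with a median of -0.41 (camera adjusted p = 4.14e-06, and 0.0330 with an estimated correlation). In the fit without replicate 2 of both basophilic groups 5 progenitor genes were higher and 6 autophagy and enucleation genes lower (1 higher), with medians of 0.15 and -0.46. Camera then gave an adjusted p of 6.47e-04 and 3.05e-04, but 0.346 for both with an estimated correlation. Of 17 heme synthesis genes, 3 were lower, Slc25a37 (-1.39), Alas2 and Fech (-1.18), and of 23 red cell membrane genes Tmod1 and Slc4a1 (-1.37) were lower (camera adjusted p = 9.81e-10 and 2.41e-13, but 0.0995 and 0.266 with an estimated correlation). Sox4, Fech and Slc4a1 lost their calls without single arrays, with adjusted p up to 0.173, 0.166 and 0.0731. The interaction count was 700 without replicate 2 of both basophilic groups, 589 with the block within each stage, 488 with array weights, 174 at an adjusted p of 0.1, 38 without the filter and 23 under quantile normalization. The higher genes were 52.5% of the 61, 69.9% with array weights, 64.4% of 45 with trended and robust variance, 38.9% of 54 under median centring and 30.4% under quantile normalization. Leaving out an array gave 12 to 36 genes (26.7% to 59.1% higher), except 282 (70.2% higher) without deficient basophilic replicate 2; the lowest, 12, came without deficient basophilic replicate 1 or deficient proerythroblast replicate 3.

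**Figure D3:**
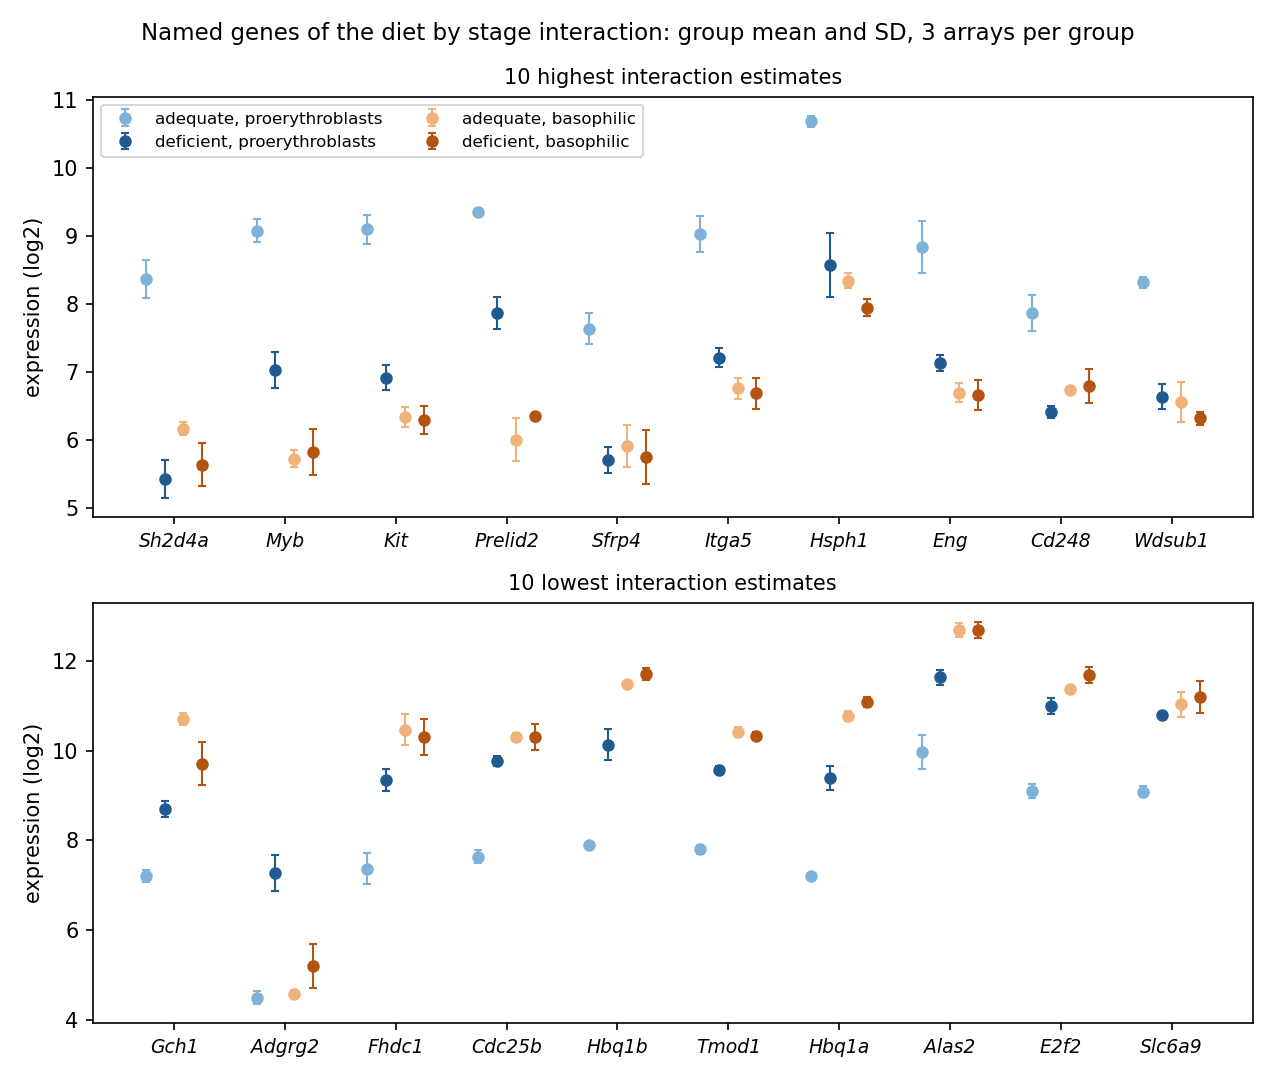
Mean expression (log2) and SD of the 4 groups, 3 arrays each, for the 10 genes with the highest and the 10 with the lowest diet by stage interaction. Kit is 9.10 in adequate and 6.92 in deficient proerythroblasts, and 6.34 and 6.30 in basophilic erythroblasts.

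The stage comparison asked how basophilic erythroblasts differed from proerythroblasts on the adequate diet. Cdk6 fell by 3.47 (SE 0.20, adjusted p = 8.62e-07), Myb by 3.35 (SE 0.19, adjusted p = 8.55e-07) and Kit by 2.76 (SE 0.16), while Hbq1b rose by 3.61 (SE 0.16), Alas2 by 2.73 (SE 0.19) and Ube2o, a ubiquitin ligase that clears proteins from maturing red cells, by 3.57 (SE 0.27, adjusted p = 3.01e-06). Among the highest were also Cyp4b1-ps2 (4.16), the interferon-induced genes Isg15 (3.63) and Rsad2 (3.37), Tcp11l2 (3.63), Gch1 (3.50), Apol11a (3.46) and Ube2h (3.35). Among the lowest were Utp4 (-3.46) and Rpf2 (-3.24) of ribosome assembly, the neutrophil gene S100a8 (-3.42), Trgc3 (-3.35), Prelid2 (-3.35), the eosinophil gene Prg2 (-3.29), Mthfd1 (-3.06) and the mitochondrial tRNA mt-Tk (-3.06). In all, 10905 genes passed, 5764 higher and 5141 lower in basophilic erythroblasts (limma, n = 3 per group), and the 20 genes named kept their calls whichever array was left out.

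Of 33 ribosome biogenesis genes 32 fell on the adequate diet, with a median of -2.26, as Utp20 (-2.73) and Polr1b (-2.93). Of 33 ribosomal protein genes 31 fell, with a median of -0.74. Of 50 genes of oxidative phosphorylation, 36 fell, such as Sdhd (-1.59). These 3 lists were lower by camera (adjusted p = 1.63e-19, 3.11e-09 and 2.55e-07), but not with an estimated correlation (adjusted p = 0.210, 0.654 and 0.678). All 5 measured globin genes rose, as did 11 of 17 heme synthesis genes, 17 of 23 red cell membrane genes (2 fell) and 17 of 26 autophagy and enucleation genes (3 fell), such as the mitophagy receptor gene Bnip3l (2.02). These 4 lists were higher by camera (adjusted p = 3.36e-04, 2.53e-04, 9.30e-06 and 1.04e-04, but 0.247, 0.408, 0.654 and 0.102 with an estimated correlation). Of 28 interferon response genes, 13 rose and 3 fell (camera adjusted p = 0.0291, but 0.654 with an estimated correlation). Of 18 progenitor genes, 9 fell and 1 rose (camera adjusted p = 0.00593, but 0.175 with an estimated correlation). Markers of other cells moved with the stage as well. Of 18 neutrophil markers 9 fell and 1 rose, and of 12 stromal markers 9 rose, with medians of -0.77 and 0.50 (camera adjusted p = 0.0329 and 0.0239, but 0.678 for both with an estimated correlation). The arrays differed in the same comparison, with a mean interquartile range of 2.64 in adequate proerythroblasts and 2.39 in adequate basophilic erythroblasts. The balance of directions moved both ways with the count, of which 52.9% were higher. It was 12560 without the filter (59.3% higher) and 12258 under median centring (62.6%), but 6694 with the stricter filter (33.0%), 6548 under quantile normalization (36.3%) and 6537 at a 1.5-fold threshold (35.9%). It was 5611 without adequate basophilic replicate 2 (35.1%), and 6190 and 6078 without adequate proerythroblast replicates 1 (36.9%) and 2 (36.5%).

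The same stage comparison was made on the deficient diet. Cdk6 fell by 2.01 (SE 0.20) and Myb by 1.20 (SE 0.19, adjusted p = 0.00133), while Hbq1a rose by 1.69 (SE 0.15), Alas2 by 1.06 (SE 0.19, adjusted p = 0.00251) and Ube2o by 2.28 (SE 0.27). The highest were Cyp4b1-ps2 (2.67), Tcp11l2 (2.58), Gvin1 (2.50), Fam220a (2.41), Oas3 (2.32), Isg15 (2.27), Tbcel (2.25), Rsad2 (2.18) and the fatty acid transporter gene Cd36 (2.16). The lowest were mt-Tk (-3.59), the immunoglobulin genes Igkv4-59 (-2.75) and Igkv4-57 (-2.56), S100a8 (-2.64), the nucleolar protein gene Nop58 (-2.59), Utp4 (-2.53), Uck2 (-2.49), Abce1 (-2.48), Ngp (-2.47) and Prg2 (-2.47). In all, 11265 genes passed, 6255 higher and 5010 lower. Igkv4-59 and Igkv4-57 lost their calls without deficient proerythroblast replicate 3 or deficient basophilic replicate 2, with adjusted p up to 0.0721 and 0.0732 (both without the former). S100a8 lost its call without either of these arrays or deficient proerythroblast replicate 1, with adjusted p up to 0.0634 (without deficient basophilic replicate 2).

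Of 42 S phase genes, 33 fell on the deficient diet, with a median of -1.21, as Cdca7 (-1.57) and Exo1 (-1.63), and 8 of 42 fell on the adequate diet, with a median of -0.55 (camera adjusted p = 5.72e-10 and 0.00593, but 0.706 and 0.736 with an estimated correlation). The difference between the diets was tested by the interaction, where none of the 42 passed (camera adjusted p = 1.66e-09, but 0.564 with an estimated correlation). Without replicate 2 of both basophilic groups 36 S phase genes fell on the deficient diet (median -0.75) and 18 on the adequate diet (median -0.32, 3 rose), and 6 were lower in the interaction. Of 33 ribosome biogenesis genes 32 fell, with a median of -1.71, and 28 of 33 ribosomal protein genes fell (camera adjusted p = 5.09e-18 and 1.28e-08, but 0.376 and 0.706 with an estimated correlation). Of 26 autophagy and enucleation genes 14 rose and 3 fell, all 5 globin genes rose, and 7 of 17 heme synthesis genes rose (camera adjusted p = 0.00308, 0.00132 and 0.0405, but 0.338, 0.428 and 0.728 with an estimated correlation). Neutrophil markers were lower, with 8 of 18 past the threshold, and stromal markers higher, with 10 of 12, as on the adequate diet (camera adjusted p = 0.00712 and 0.0141, but 0.780 and 0.830 with an estimated correlation). Of 14 B cell markers 3 fell, with a median of -0.54 (camera adjusted p = 0.0393, but 0.830 with an estimated correlation). The mean interquartile range of the arrays was 2.62 in deficient proerythroblasts and 2.35 in deficient basophilic erythroblasts. The balance of directions moved here too, from 55.5% higher. The count was 13982 without the filter (64.1% higher) and 11670 under median centring (7006 of them higher), but 6350 with the stricter filter (31.4%), 6882 at a 1.5-fold threshold (41.4%) and 2929 with the arrays of this contrast alone (23.4%). It was 6845 without deficient proerythroblast replicate 1 (51.9%) and 4951 without replicate 3 (40.1%).

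**Figure D4:**
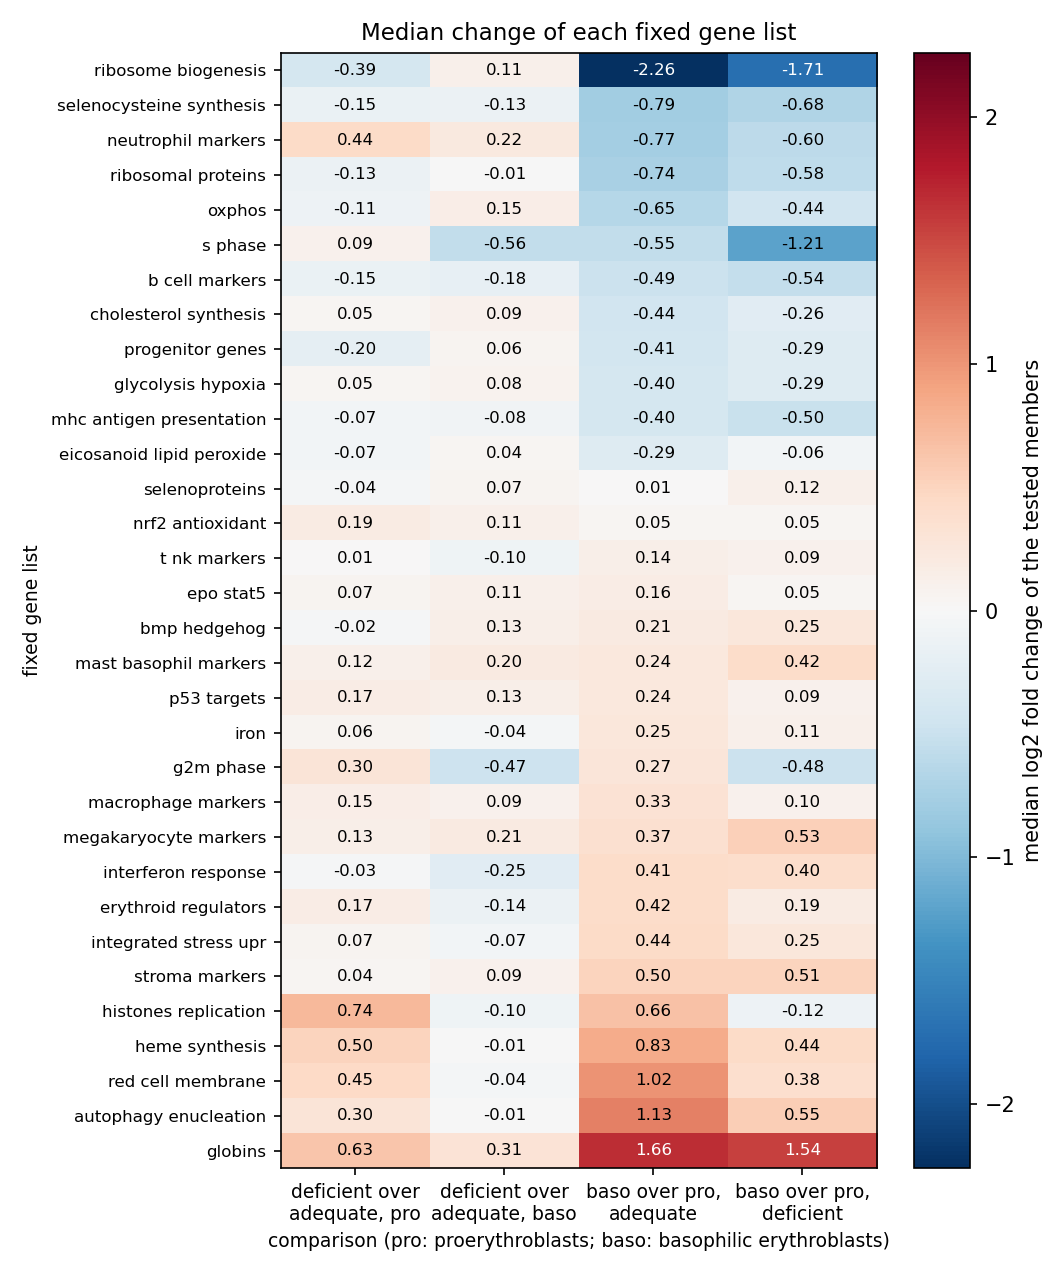
Median log2 fold change of the tested members of each fixed gene list (rows) in the diet and stage comparisons (columns), with red for higher and blue for lower values. Ribosome biogenesis has the lowest median, -2.26, in basophilic over proerythroblasts on the adequate diet, and globins the highest, 1.66.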

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

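The tests of array background, of a share of basophilic cells and the genes beyond its bound, of a compressed signal range, and of all splits that part every pair of replicate numbers were chosen only after the result was seen.

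The diet effect differed between the stages in 61 genes by the interaction test. It was higher in basophilic erythroblasts for Sh2d4a (2.41), Myb (2.15), Kit (2.13), Prelid2 (1.83), Sfrp4 (1.76), Itga5 (1.76), Hsph1 (1.73), Eng (1.66), Cd248 (1.52) and Wdsub1 (1.44). It was lower there for Gch1 (-2.49), Adgrg2 (-2.16), Fhdc1 (-2.15), Cdc25b (-2.11), Hbq1b (-2.03), Tmod1 (-1.88), Hbq1a (-1.88), Alas2 (-1.67), E2f2 (-1.58) and Slc6a9 (-1.55). Of 100 splits of the arrays, 8, the real one included, gave an interaction count as large as the real 61, and the highest other split gave 1000, so chance is not excluded by this count. The 7 others keep the real grouping of the proerythroblasts and so still hold its diet effect. Swapping the basophilic diets, for example, turns the interaction into the diet effect over both stages, with 515 genes. None of the 87 splits that regroup the proerythroblasts gave as many, the highest 13.

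For the diet effect over both stages, 3 of 100 splits, the real one included, gave as many genes as the real 515, and the highest other gave 1000. The other 2 keep the real proerythroblast grouping and put both basophilic replicate 2 arrays together. Should the replicate numbers pair the arrays across diets, 32 splits part every pair. The basophilic arrays do not show such a pairing for replicates 1 and 3. Of these 32 splits 1, the real one, gave as many (3.1%), the highest other 246. The 24 that regroup the proerythroblasts gave 0, so the share rests largely on the diet effect in proerythroblasts. It cannot exclude chance for an effect over both stages. For the interaction 4 of these 32 (12.5%) gave as many, all with the real proerythroblast grouping, the highest other 515. The comparisons of 3 against 3 arrays have 10 splits, too few for a share under 0.05. There 1 of 10 splits, the real one, gave as many genes in each: 810 against at most 14 for the diet in proerythroblasts, 4 against 0 for the diet in basophilic erythroblasts, 10905 against 0 for the stage on the adequate diet and 11265 against 0 for the stage on the deficient diet.

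The diet effect in proerythroblasts followed the stage effect: of the 255 genes that rose, 145 also rose and 3 fell from proerythroblasts to basophilic erythroblasts on both diets, and of the 555 that fell, 332 also fell and 0 rose. Noise of the shared arrays is argued against, since the correlation with the mean stage effect of both diets was 0.446 and at most 0.178 in size in 100 simulations without a diet effect. So is the GC background of the arrays, whose diet difference was -3.7% of the stage difference. For the interquartile range this value was 9.0%, in the stage direction. The array medians were 5.13, 5.15 and 5.17 in adequate and 5.2, 5.28 and 5.22 in deficient proerythroblasts. Those of the basophilic arrays ran from 5.3 to 5.55, and the lower quartiles moved the same way. A shift of the array values other than in background therefore stays open. Basophilic cells among the sorted deficient proerythroblasts may account for the pattern. For 338 genes at least 4-fold lower in basophilic cells on the adequate diet the best share was 44.8%. The spread was 1.56 times that expected from the errors. On leaving out an array this ratio ran from 1.30 (without adequate proerythroblast replicate 2) to 2.20 (without deficient basophilic replicate 2). These values lie on both sides of the limit of 1.5. Deficient basophilic replicate 2, which stood apart, enters the ratio only through the error shared by all groups. Without it the 338 genes and the share of 44.8% were unchanged. All ratios under 1.5 came from fits that kept it, so they cannot count in favour of a single share. The ratio of 2.20 goes against a single share as the whole cause. It rests on leaving out this array, so such a mixture stays open. The choice of genes planned first, on both diets, gave 0.98 and 28.4%, but it removes genes that fell most and was replaced. The 338 genes were chosen with the adequate proerythroblast arrays that also enter the diet effect. Noise in these arrays can therefore raise the share of 44.8%. Beyond what that share allows fell 2 genes, Sh2d4a and Kit (1 to 4 on leaving out an array). Earlier maturation of proerythroblasts on the deficient diet stays open as a biological explanation and was not tested apart from such a mixture.

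Replicate 2 of both basophilic groups stood apart in background and range. After removing the level of the gene, the deviation correlated with the stage effect at 0.41 on the adequate and 0.47 on the deficient diet. This direction is away from proerythroblasts and argues against cells of an earlier stage. The test was not made for cells of a later stage, which stay open. For cells of another lineage, 0 of the 7 lists of other-cell markers lay above the 99th percentile of random lists on both diets. The stromal list lay above it on the adequate diet (99.2, median deviation 0.18) and at 97.0 on the deficient diet (0.20). Missing the limit on 1 diet does not count against stromal cells, so the test leaves them open. The deviation correlated with the level of the gene at -0.45 (adequate) and -0.50 (deficient), which restates the narrower range that set these arrays apart and so cannot show whether a compressed signal was the cause. The deviations of the 2 diets correlated at 0.78, and the source stays open.

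Features outside the gene comparisons also held a diet signal. Among 944 tested features that name several genes, 38 passed for the diet in proerythroblasts (10 higher, 28 lower) and 19 over both stages. Among 19077 tested features with no gene named, 28 passed in proerythroblasts (7 higher, 21 lower) and 1 over both stages.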

How the results depend on the processing

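Leaving out replicate 2 of both basophilic groups, and blocking the replicate number within each stage, were chosen after seeing the data. Over 942 results for named genes, the alternatives gave 22988 values on the same side of the threshold, 769 that newly passed, 882 that no longer passed and 0 called values that reversed.

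Counts within 1.5 times the reported one are left out below. Without the filter the interaction count was 38. The stricter filter, which tests fewer genes, gave 6694 for the stage effect on the adequate diet and 6350 on the deficient diet. Quantile normalization gave 50 for the diet in basophilic erythroblasts, 6548 for the stage on the adequate diet and 23 for the interaction. Array weights gave 8008 (diet in proerythroblasts), 155 (in basophilic erythroblasts), 2469 (both stages) and 488 (interaction). The replicate block gave 19 in basophilic erythroblasts and 876 over both stages, and the block within each stage 2233 in proerythroblasts, 295 in basophilic erythroblasts, 2049 over both and 589 for the interaction. Without replicate 2 of both basophilic groups these were 3285, 420, 2303 and 700. A 1.5-fold threshold gave 307 over both stages, 6537 for the stage on the adequate and 6882 on the deficient diet. An adjusted p of 0.1 gave 1286, 7, 931 and 174 for the diet in proerythroblasts, in basophilic erythroblasts, over both and the interaction. The arrays of the contrast alone gave 2417 for the diet in proerythroblasts, 0 in basophilic erythroblasts by limma (1304 genes had an unadjusted p under 0.05 in the fit of all arrays) and 2929 for the stage on the deficient diet. Of the list tests, 86 passed with camera, 51 with fry, 4 with an estimated correlation, and 0 with that and without replicate 2 of both basophilic groups. The block within each stage can estimate 4 of the 6 comparisons, where 51 list tests passed against 53. For the diet in proerythroblasts, fits without basophilic arrays hold the same estimates (median log2 fold change 0.017). Their counts differ only through the error estimate, which all groups share, and its degrees of freedom. For the other changes, apart from the thresholds and the stricter filter, the cause was not tested.

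Leaving out 1 array gave 314 to 1808 genes for the diet in proerythroblasts, 0 to 289 in basophilic erythroblasts, 245 to 1505 over both stages, 5611 to 14331 for the stage on the adequate and 4951 to 12406 on the deficient diet, and 12 to 282 for the interaction. The highest diet and interaction counts came without deficient basophilic replicate 2. The lowest came without adequate proerythroblast replicate 1 for the diet in proerythroblasts (314) and over both stages (245). The background of the basophilic arrays, up to 4.70 against at most 3.53 in proerythroblasts, limits what dim genes can show.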

Other observations

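The test of selenium-responsive selenoproteins and the fit without replicate 2 of both basophilic groups were chosen only after the result was seen.

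Beyond the groups above, Ppp1r15a, which ends the integrated stress response, rose by 1.48 (SE 0.16, adjusted p = 7.11e-04) in deficient proerythroblasts, and Eif2ak1, the heme-regulated kinase that starts it, by 0.89 (SE 0.13, adjusted p = 0.00349), while the disulfide isomerase gene Pdia6 fell by 0.82 (SE 0.14, adjusted p = 0.00761). Of 31 genes of the integrated stress and unfolded protein responses 4 rose and 1 fell there (5 and 3 adjusted over the list alone; camera adjusted p = 0.157). Of 28 interferon response genes Lgals3bp (-1.07) and Bst2 (-1.20) fell (camera adjusted p = 0.318), Bst2 with an adjusted p up to 0.0718 on leaving out an array. Of 20 BMP and hedgehog genes Kit alone fell (camera adjusted p = 0.221). Of 19 eicosanoid and lipid peroxidation genes 1 fell, the phospholipase gene Pla2g4a (-0.88, camera adjusted p = 0.21). Of 19 cholesterol synthesis genes Dhcr7 (-0.51) fell, and of 15 antigen presentation genes Psmb10 (-0.85), with camera adjusted p = 0.713 and 0.213. These 3 calls ended without single arrays, at adjusted p up to 0.0596, 0.155 and 0.154. Of 32 glycolysis and hypoxia genes Bpgm (0.82) rose and Tpi1 (-0.77) and Egln1 (-0.57) fell (camera adjusted p = 0.765), with adjusted p up to 0.117, 0.126 and 0.14 without single arrays.

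Of 51 genes of G2 and mitosis none passed in proerythroblasts (median 0.30), nor did any of 33 ribosomal protein genes (-0.13) or 50 oxidative phosphorylation genes (-0.11). Camera gave adjusted p = 0.00587, 0.0055 and 0.0365, but 0.772, 0.739 and 0.772 with an estimated correlation. These medians use the proerythroblast arrays alone, so leaving out replicate 2 of both basophilic groups changes only the error. In that fit 22 genes of G2 and mitosis rose and 1 fell, 1 ribosomal protein gene fell and 5 oxidative phosphorylation genes fell. Of 42 S phase genes Cdca7 (-0.62) fell (camera adjusted p = 0.255), with an adjusted p up to 0.0938 without single arrays. Of 11 megakaryocyte markers Itga2b (0.75) rose (camera adjusted p = 0.21), with an adjusted p up to 0.137 without single arrays. None of 18 macrophage, 14 B cell, 14 T and NK cell, 12 stromal or 5 mast cell and basophilic granulocyte markers passed there (camera adjusted p = 0.157, 0.713, 0.819, 0.493 and 0.157).

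Among selenoprotein genes, 4 are known from other tissues to lose transcript at low selenium: Gpx1, Selenow, Selenoh and Msrb1. Over both stages their mean diet effect was -0.45, against 0.10 for the other 17, a difference of -0.55 (exact one-sided permutation p = 3.34e-04, 5985 permutations). A candidate explanation is that the diet lowered the transcripts most sensitive to selenium. The 4 genes were picked after their values were seen, so the p-value cannot be read as a test on fresh data.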
